A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

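Total RNA from the lungs of female A/J mice was profiled on 8 arrays of a custom multi-organism miRNA oligonucleotide design. Per the labels' protocols, the RNA of a sample was ligated to a linker carrying the dye DY547, and pooled synthetic DNA oligonucleotides for a subset of mammalian miRNAs, carrying an Alexa Fluor dye, served as the reference in the second channel. Groups came from the sample titles: 3 control arrays, 4 arrays of vinyl carbamate (VC) and 1 array of VC with indole-3-carbinol (VC+I3C). The labels call the tissue lung tumor on every array, controls included, while the extraction protocol names lung tissue. A descriptive field also names a human cell line as a source of RNA, in conflict with the other fields, and was not used. The labels do not say whether an array held 1 mouse or a pool, so the p-values measure the spread between these arrays, which may be technical.

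Per the file headers, BlueFuse for Microarrays 3.4 quantified 4704 spots per array and combined them into 1147 rows. The deposited amplitudes are linear intensity values of each channel. The deposited log2 ratio of sample over reference and the deposited log2 product of both channels were used as given and show no centring. Other deposited columns hold the sum and product of the channels, the SD between replicate spots and P ON, a probability that a probe carries signal in a channel. No background correction was applied, because this software is known to fit the signal apart from the local background. That step was taken from knowledge of the software and is not given in the sources used here, so the normexp correction fixed before the data were examined was not applied and its alternatives were not run.

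The amplitude columns did not add up to the deposited sum, within a tolerance of 1, in 35 rows on control 1, the fewest, and 106 on control 2, the most. For miR-31 on control 2 and VC 2 both amplitudes were exactly 100, while the log2 ratio column kept values of -2.98 and -1.88. The log2 ratio and log2 product columns were therefore chosen for the main values after this was seen, and the ratio of the amplitude columns was run as an alternative. The authors' value table held the log2 of the sample amplitude minus 1 constant per array, which varied by at most 0.0141 within an array. Its log2 scale and its direction follow from that match, it does not use the reference channel, and how its centring was chosen is not given in the sources used here. The medians of its columns were -1.37, -1, -1.62, -1.39, -1.33, -1.38, -1.29 and -1.57 for control 1 to 3, VC 1 to 4 and VC+I3C.

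Of the 1147 rows, 1052 carried miRNA names and 713 named a mouse, human or rat miRNA. A probe was tested when P ON of the sample channel was at least 0.5 on at least 3 of the 8 arrays, which left 191 probes for 160 mature miRNAs. P ON stood in for a rule on the background SD, a measure not used here, and the cutoff of 0.5 was set after the files were seen. Of the 191 tested probes, 20 did not reach this cutoff in the reference channel on 3 arrays, so their ratios rest on a dim reference. Log2 ratios were normalized within each array by loess (span 0.3) in limma 3.58.1 under R 4.3.3, with rows that name no miRNA at weight 0. One limma fit over all 8 arrays with 3 group means gave the comparisons, with two-sided tests and Benjamini-Hochberg adjustment over the 191 probes at a threshold of 0.05. The single VC+I3C array was assumed to vary like the other groups. A miRNA not above background on any array of a group was given only as a bound on the sample channel after loess and Aquantile normalization, which is open to dye bias because no dyes were swapped.

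Before the data were examined, 19 miRNA lists were fixed, and 11 had at least 3 tested members. The 8 lists with fewer were the miR-183 cluster, the miR-34 and miR-449 family, striated muscle, endothelial, erythroid, neural, liver and pancreas, and the embryonic stem cell cluster. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with 1 probe per mature miRNA, the mouse-named one where it existed. The rule for named miRNAs, also fixed before, took those with the largest changes among those past the threshold or, where fewer than 5 passed in a direction, the 5 with the smallest p, and 3 for the VC+I3C comparisons. It added the members of each list with the smallest p and 8 miRNAs always named, miR-21, miR-31, miR-130a, miR-146b, miR-377, miR-1, miR-143 and let-7a. These 8 came from knowledge of this study and of lung tumours and are not independent evidence of a direction.

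The file headers gave 4 scan days. Control 1 and VC 1 shared day 1, control 2 and VC 2 day 2, control 3 and VC 3 day 3, and VC 4 and VC+I3C day 4. Comparisons were therefore also fitted with scan day as a block and computed within days. Under the block, VC against control rests on days 1 to 3 and leaves out VC 4, and VC+I3C against VC is the difference from VC 4 alone. Day 4 holds no control array. The blocked VC+I3C against control therefore adds the VC against control difference of days 1 to 3 to the difference from VC 4. The ratio of signal to background in the sample channel lay between 11.1 on control 2 and 17.65 on VC 4, per the file headers, and the number of arrays limits the precision. Other header measures ranked the arrays differently. The median log2 SD between replicate spots was lowest on VC 1 (0.37) and highest on control 2 (0.81), VC 3 (0.82) and VC 4 (0.83). Spots of the lowest confidence made up 42.07% on VC 1, the fewest, 67.62% on VC 4, 70.28% on VC 3 and 73.34% on control 2, the most. The fit was tested on simulated data for VC against control with 191 probes and 100 simulations. It recovered 6.15% of 2-fold, 43.2% of 4-fold and 77.85% of 8-fold changes, with 3.56% of calls false. Each simulation changed 20 probes of each size at once and drew independent noise without scan day effects. Recovery may therefore be lower for a few changed miRNAs in these data. Intervals of correlations across miRNAs are 95% intervals from 2000 bootstrap resamples. Other settings covered normalization, the filter on dim probes, the columns used, the authors' table, array weights, the variance prior, blocks and each array left out.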

Results

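The miRNA content of mouse lung was measured after the carcinogen vinyl carbamate, alone or followed by a diet with indole-3-carbinol, a compound formed from cruciferous vegetables. Mice received 2 injections of 0.32 mg VC each, 1 week apart, and the I3C diet ran for 15 weeks. The treatment arms held 10 control mice, 20 VC mice and 15 VC+I3C mice, and 3, 4 and 1 arrays were measured, so the I3C diet had no replicate. Mean sample amplitude was between 1168 and 1712 on the 4 arrays of scan days 1 and 2 and between 434 and 596 on the 4 arrays of scan days 3 and 4. Of the 191 tested probes, 104 were above background on the VC+I3C array, the fewest, and 187 on VC 1, the most.

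Arrays did not fall together by treatment. Across the 191 probes, which are not independent replicates, control 1 correlated best with VC 1 (Pearson r = 0.94) and control 2 with VC 2 (r = 0.90), each pair from 1 scan day. Control 3 correlated best with the VC+I3C array (r = 0.95), ahead of VC 4 (r = 0.94) and of VC 3 from its own day (r = 0.89). Only VC 3 correlated best with an array of its own group, VC 4 of another day (r = 0.91). The mean r was 0.91 over the 3 pairs of control and VC from the same day and 0.81 over the 9 pairs of the same group. In the main setting 4 of the 8 arrays correlated best with an array of their own day, against 2 of 8 with the authors' values.

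**Figure D1:**
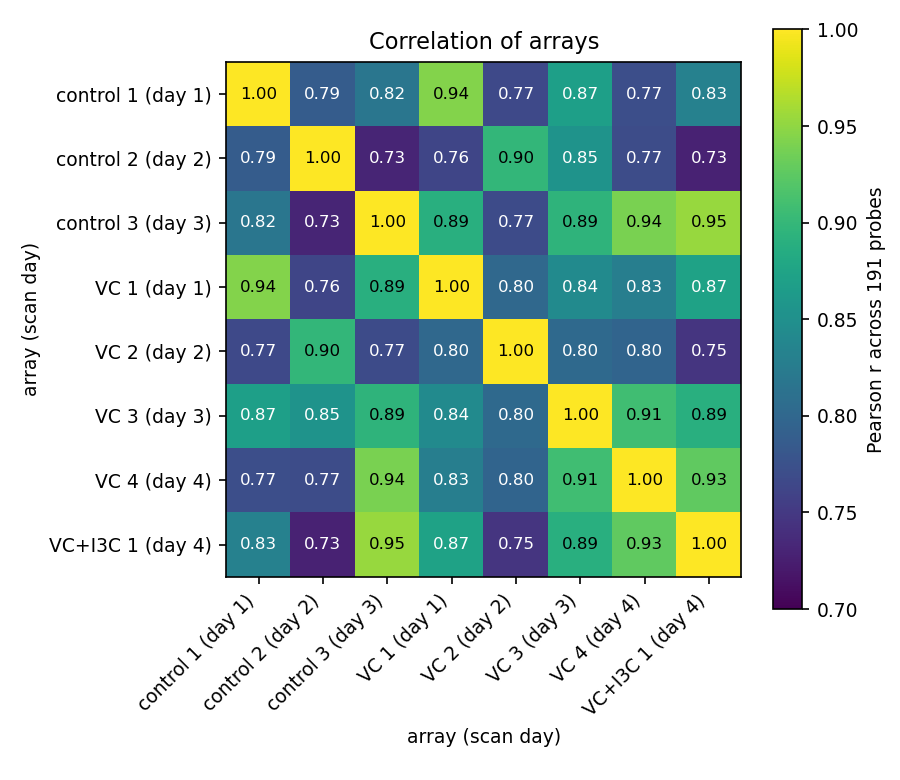
Pearson correlation (colour and printed value) between each pair of the 8 arrays across 191 probes, with scan days given beside the array names. Control 1 with VC 1 (0.94) and control 2 with VC 2 (0.90) are closest within their day, and control 3 is closest to the VC+I3C array (0.95).

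The first comparison asked which miRNAs differ between lungs of VC-treated and control mice. Several miRNAs linked to lung tumours had higher mean values in VC, but no miRNA passed the test. miR-21 had a log2 ratio of 1.64 ± 1.34 (SD, n = 3) in control and 2.38 ± 0.46 (SD, n = 4) in VC, a difference of 0.74 (SE 0.66) or 1.67-fold. Without control 1 the difference was 0.11 and without control 3 it was 1.45. The difference was 0.53 (SE 0.57) for miR-31, 0.28 (SE 0.48) for miR-130a and 0.30 (SE 0.71) for miR-146b. It was 1.01 (SE 1.05) for miR-377, which was above background on 1 of 3 control and 3 of 4 VC arrays. The muscle miRNA miR-1, above background on 1 of 3 control and 2 of 4 VC arrays, differed by -0.61 (SE 0.65), the smooth muscle miRNA miR-143 by -0.09 (SE 0.67) and let-7a, which targets Ras transcripts, by 0.10 (SE 0.86). With scan day as a block the sign turned for miR-146b (-0.20) and let-7a (-0.43), and on the ratio of the amplitude columns it turned for miR-31 (-0.24). Over all settings tried, miR-21, miR-130a and miR-377 kept their sign and the other 5 turned in at least 1. In limma 0 of 191 probes passed, with an adjusted p of 0.995 for each of these 8 miRNAs, and 1 probe had an unadjusted p under 0.05, where chance gives 9.55. With the scan day block 0 probes passed and 0 had an unadjusted p under 0.05.

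**Figure D2:**
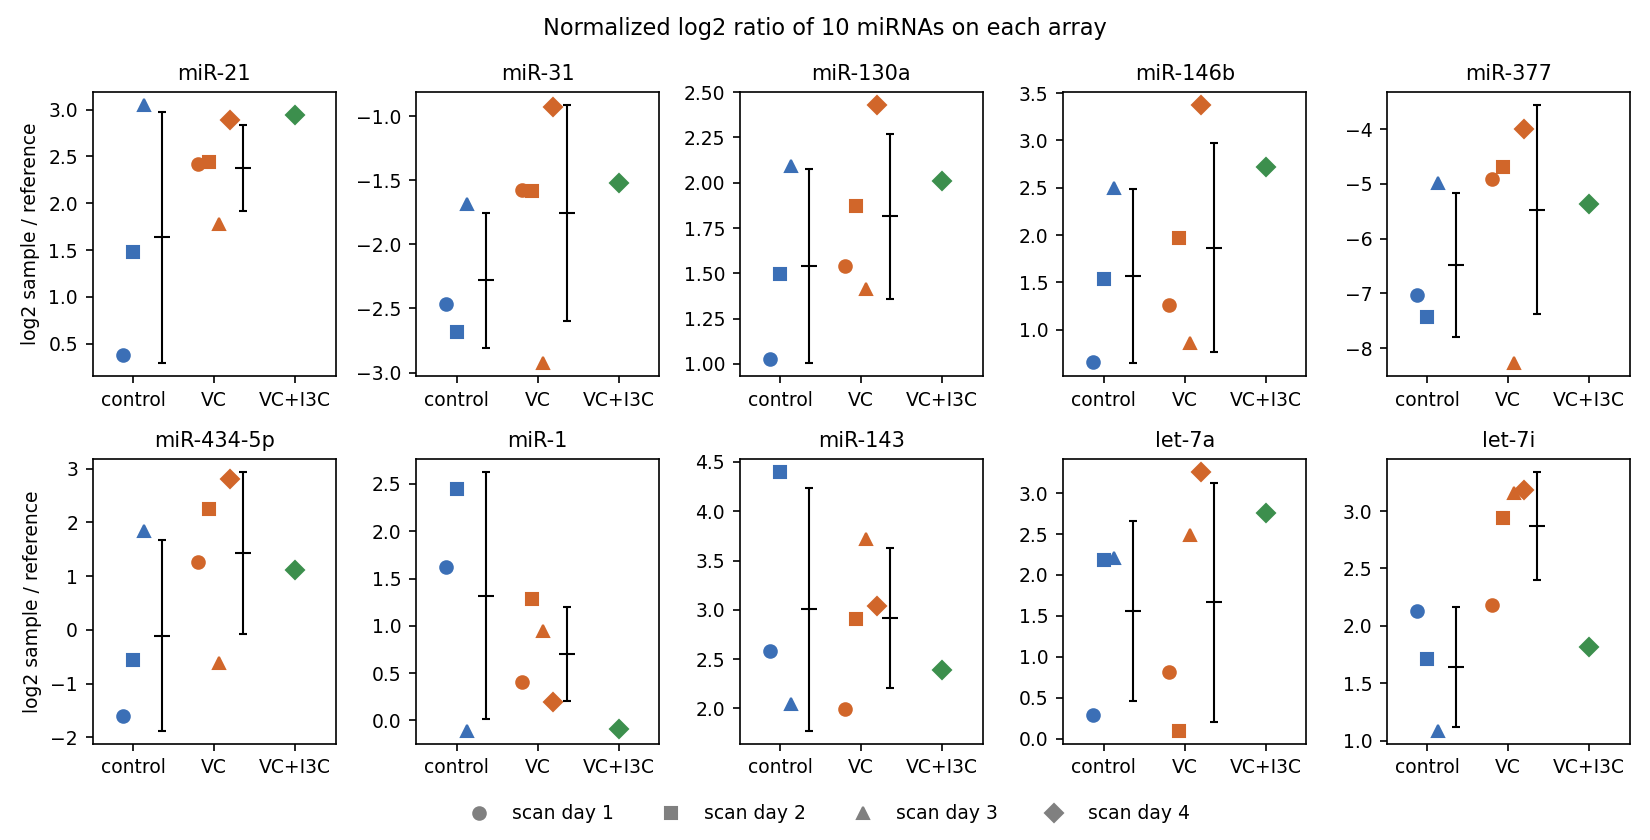
Normalized log2 ratio of sample over reference for 10 miRNAs on each array; colours mark control (n = 3), VC (n = 4) and VC+I3C (n = 1), mark shapes the scan day, and bars the mean ± SD. For miR-21 the control arrays lie at 0.38, 1.48 and 3.05 and the VC arrays between 1.77 and 2.89, so the groups overlap.

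The miRNAs with higher values in VC and the smallest p were let-7i, miR-674, miR-144, the human-named hsa-miR-591 and miR-23a, and none passed. let-7i was 1.64 ± 0.52 (SD, n = 3) in control and 2.87 ± 0.47 (SD, n = 4) in VC, a difference of 1.23 with a 95% interval from 0.14 to 2.32 (limma, adjusted p = 0.995). A let-7i probe named for fish and cattle lay outside the tested probes and was above background on all 8 arrays. That probe was 0.56, 1.26 and -0.13 on control 1 to 3. On VC 1 to 4 it was 0.57, 1.53, 0.71 and 0.97, so its groups overlapped. miR-674 differed by 0.92 (SE 0.46), the erythroid miR-144 by 1.33 (SE 0.68), hsa-miR-591 by 1.31 (SE 0.71) and miR-23a by 0.95 (SE 0.56). miR-144 was above background on 4 of the 8 arrays and differed by -0.15, 3.21 and 0.44 on scan days 1, 2 and 3. Of these 5, miR-674 alone kept its sign on the sample amplitude column used without the reference, after quantile normalization and in the authors' table. In these settings let-7i was -0.20 and -0.23, and miR-23a -0.27 and -0.23. With the sample channel taken from the sum and product columns, let-7i and miR-23a turned too. No turn was found there for miR-144 or hsa-miR-591. On the ratio of the amplitude columns hsa-miR-591 turned as well. All VC arrays lay above all controls for 3 of 160 miRNAs (let-7i, miR-674 and miR-181c), where chance gives 4.57, and below them for 0. Lower values with the smallest p were those of miR-532, miR-721, miR-701, miR-365 and miR-1. miR-532 was 1.59 ± 0.61 (SD, n = 3) in control and 0.39 ± 0.73 (SD, n = 4) in VC, above background on 2 arrays of each group, a difference of -1.20 (SE 0.55) with an adjusted p of 0.995 in limma. miR-721 differed by -1.14 (SE 0.86), miR-701 by -0.64 (SE 0.55) and miR-365 by -0.79 (SE 0.82).

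Among the fixed lists, 0 members passed in limma over all probes and 0 when adjusted over the list alone. In the Dlk1-Dio3 imprinted cluster, a group of maternally expressed miRNAs, 7 of 9 tested members had higher values in VC, with a median of 0.91. miR-434-5p differed by 1.53 (SE 1.01). hsa-miR-154* and miR-299 were not above background on any control array, and no bound over 1-fold could be given. Both met the rule of 3 arrays only through arrays of VC-treated mice, which favours higher values in VC. In the list raised in lung cancer, 18 of 20 members had higher values, with a median of 0.32; it holds 5 of the miRNAs chosen from knowledge of this study and is no independent evidence of a direction. Of its members, miR-222 differed by 0.95 (SE 0.58) and miR-19b by 0.73 (SE 0.59). miR-222 was above background on only 3 of the 8 arrays and differed by -0.42, 2.44 and 0.91 on scan days 1, 2 and 3. With the sample channel taken from the sum and product columns miR-222 turned to -0.88. Neither list passed in camera (adjusted p = 0.173 for both, 0.940 for both with an estimated correlation and 0.322 for both with the scan day block). The Dlk1-Dio3 list passed when control 3 was left out (median 1.57, adjusted p = 0.0110) and when VC 3 was left out (median 1.65, adjusted p = 0.000998). With an estimated correlation the adjusted p values were 0.948 and 0.642. Of the 9 members, 1 was above background on all 8 arrays and most on only 3 or 4, so these passes rest largely on dim probes.

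All 5 tested members of the miR-200 family, which represses Zeb transcription factors and marks epithelium, had higher values in VC, with a median of 0.53 (camera, adjusted p = 0.362). With the scan day block the median was 0.14 (adjusted p = 0.906), and on scan day 3 0 of 5 members had higher values, with a median of -0.36. miR-200b differed by 0.53 (SE 0.54) and miR-141 by 0.40 (SE 0.43). With the sample channel alone the family passed after quantile normalization (adjusted p = 0.0284) and in the authors' table (adjusted p = 0.00629), and with an estimated correlation the adjusted p values were 0.525 and 0.420. The other 8 tested lists had adjusted p values between 0.691 and 0.953 in camera. In the let-7 family 3 of 8 members had higher values, with let-7d at -0.37 (SE 0.53) and miR-98 at -0.31 (SE 0.41). In the miR-17 cluster and its paralogs, which Myc induces, 8 of 11 did, with miR-17-5p at 0.62 (SE 0.59) and miR-20a at 0.56 (SE 0.63). Higher values were found for 3 of 3 members of the miR-29 family, with miR-29c at 0.32 (SE 0.40), and 4 of 5 of the miR-30 family, with miR-30a-5p at 0.27 (SE 0.41). The sign of miR-20a and miR-29c turned with the sample channel alone (-0.19 and -0.01). Of lists for other cell types, the smooth muscle and fibroblast list had 4 of 6 members higher, with miR-199a* at 0.55 (SE 0.74), and the myeloid and lymphoid list 1 of 3, with miR-223 at -0.08 (SE 0.51). The inflammation-induced list had 3 of 3 higher, with a median of 0.30, and the list lowered in lung cancer 23 of 33, with miR-338 at 0.90 (SE 0.55). With the scan day block the median turned to -0.11 for the inflammation-induced list and from -0.08 to 0.08 for the myeloid and lymphoid list. The median difference of all 191 probes was 0.18 after loess, 0.10 after median centring and -0.03 in the authors' table, and values are to be read against these shifts.

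Within scan days, differences between VC and control had one sign on days 1 and 2 and the opposite sign on day 3 for several of these miRNAs. Among miRNAs above background on all 8 arrays, on days 1, 2 and 3 they were 2.04, 0.96 and -1.28 for miR-21, 0.52, 0.37 and -0.68 for miR-130a, 0.60, 0.44 and -1.64 for miR-146b and -0.59, -1.49 and 1.67 for miR-143. Not all named miRNAs followed: let-7a, also above background on all 8 arrays, had 0.52, -2.09 and 0.28, and let-7i had 0.05, 1.23 and 2.07. The median of the Dlk1-Dio3 list was 2.07, 2.74 and -2.46, with 7, 8 and 2 of 9 members higher in VC. However, 6 of the 9 were not above background on control 1, control 2 or VC 3, so the size of these medians is not exact. hsa-miR-154* and miR-299 were not above background on control 3, so the sign of their day 3 differences is uncertain too. The smooth muscle and fibroblast list went the other way, with 2, 0 and 6 of 6 members higher and medians of -0.28, -0.55 and 1.05, and in the list lowered in lung cancer 14, 13 and 27 of 33 members were higher. Across 160 miRNAs, which are not independent replicates, days 1 and 2 correlated at r = 0.45 (95% interval 0.26 to 0.59), days 1 and 3 at r = -0.55 (-0.68 to -0.39) and days 2 and 3 at r = -0.50 (-0.64 to -0.34). Each day holds 1 array per group. Without control 3 and VC 3, a setting chosen after seeing the data, 0 of 191 probes passed in limma (smallest adjusted p = 0.222, 11 with an unadjusted p under 0.05), and the Dlk1-Dio3 list passed in camera with a median of 2.34 (adjusted p = 6.91e-06, and adjusted p = 0.339 with an estimated correlation).

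**Figure D3:**
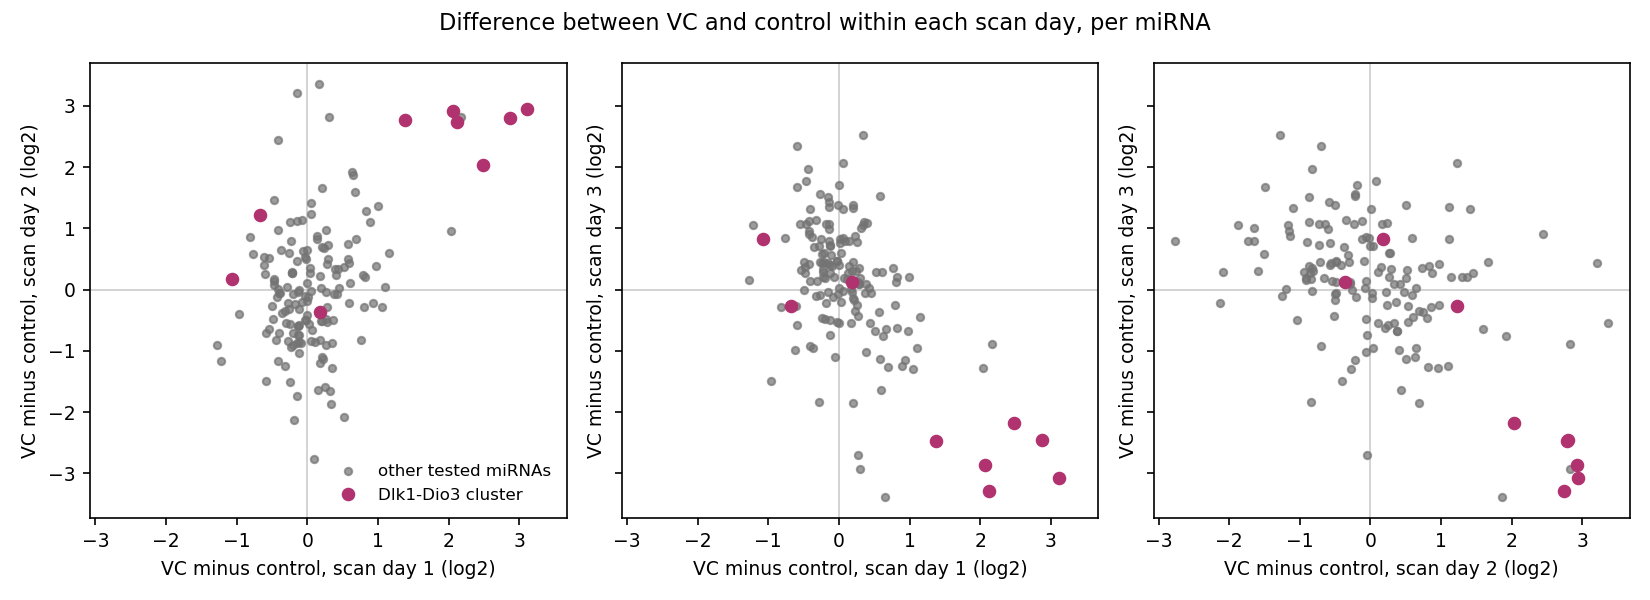
Log2 difference between the VC and the control array of 1 scan day plotted against that of another, 1 point for each of 160 miRNAs, with the 9 Dlk1-Dio3 members marked. Days 1 and 2 correlate at 0.45, and day 3 correlates at -0.55 with day 1 and at -0.50 with day 2.

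The second comparison set the 1 array of VC mice fed I3C against the VC arrays and describes that array, not the diet. miR-709 was 0.67 on the VC+I3C array and -0.98 ± 0.60 (SD, n = 4) in VC, a difference of 1.65 (SE 0.70) that did not pass. miR-21 was 2.95, a difference of 0.57 (SE 0.96), and let-7i 1.82, a difference of -1.05 (SE 0.70). The difference was 0.23 (SE 0.84) for miR-31, 0.20 (SE 0.70) for miR-130a, 0.85 (SE 1.04) for miR-146b, -0.52 (SE 0.99) for miR-143 and 1.10 (SE 1.26) for let-7a. The other miRNAs with the smallest p, miR-365 and miR-216a with higher and miR-148a, miR-687 and miR-532 with lower ratios, were not above background on the VC+I3C array and no bound over 1-fold could be given. In limma 0 of 191 probes passed (smallest adjusted p = 0.936, 4 with an unadjusted p under 0.05), and with the scan day block 0 passed and 9 had an unadjusted p under 0.05. On the ratio of the amplitude columns 1 probe, miR-101a, passed with a difference of 6.79 (adjusted p = 0.00410), against 0.19 in the main setting. Its reference amplitude on the VC+I3C array was exactly 100, while the deposited sum of both channels was 6373.

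Against VC 4, the VC array of the same scan day, all 5 members of the miR-200 family had lower values, with a median of -0.68 and miR-200a at -2.18. In the list raised in lung cancer 18 of 20 members had lower values, with a median of -0.61, and in the Dlk1-Dio3 list 7 of 9, of which 6 were not above background on the VC+I3C array. Values were also lower for 25 of 33 members of the list lowered in lung cancer, with a median of -0.49, for 10 of 11 of the miR-17 cluster and its paralogs and for 7 of 8 of the let-7 family. miR-377 was not above background on the VC+I3C array and was at least 1.47-fold lower than on VC 4. The difference was 0.06 for miR-21 and -0.65 for miR-143, and compared with the difference from all 4 VC arrays the sign turned for miR-31 (-0.60), miR-130a (-0.42), miR-146b (-0.66) and let-7a (-0.49). The median over all 191 probes was -0.43, a general shift between these arrays against which the values of the lists are to be read. No list passed in camera against the 4 VC arrays (smallest adjusted p = 0.737) or with the scan day block (smallest adjusted p = 0.341).

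Against the 3 control arrays, miR-467a was -0.10 on the VC+I3C array and -1.65 ± 0.37 (SD, n = 3) in control, and miR-706 was 1.48 against 0.11 ± 0.17 (SD, n = 3). Neither passed (limma, adjusted p = 0.925 for both). miR-21 differed by 1.31 (SE 0.99), miR-31 by 0.76 (SE 0.87) and miR-146b by 1.16 (SE 1.08), and with the scan day block the sign turned for miR-31 (-0.35) and miR-146b (-0.86). The other miRNAs with the smallest p, miR-144 with a higher and miR-532, miR-687 and miR-148a with lower ratios, were not above background on the VC+I3C array. In limma 0 of 191 probes passed, 6 had an unadjusted p under 0.05, and with the scan day block 0 passed and 2 had an unadjusted p under 0.05. On the ratio of the amplitude columns miR-101a passed here too, with a difference of 7.13 (adjusted p = 0.00362). The Dlk1-Dio3 list did not pass in camera (adjusted p = 0.392, and adjusted p = 0.572 with the scan day block). It passed without control 3 and VC 3 (adjusted p = 0.00420, and adjusted p = 0.808 with an estimated correlation), where 6 of its 9 members were not above background on either remaining control array or on the VC+I3C array. Since no miRNA was called between VC and control, a share of called miRNAs nearer to control on the VC+I3C array could not be computed.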

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

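Among the 4 VC arrays, 1 array stood apart from the others for 5 of 53 values examined, where chance gives about 1 in 20. On VC 1 miR-23a was 4.25 against 5.88 to 6.07 on the other VC arrays, miR-29a 4.09 against 6.03 to 6.42, and miR-199a* 2.07 against 3.80 to 4.11. Control 1 of the same scan day had 4.39, 4.31 and 1.87 for these miRNAs. On VC 3 miR-141 was 2.02 against 2.76 to 2.90, and on VC 2 miR-142-5p was 2.35 against -0.51 to -0.17.

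Of 122 rows for other species, controls or added sequences that were above background on at least 3 arrays, 4 had every VC array above every control array, where chance gives 3.49. The gap on the log2 scale between the lowest VC and the highest control array was 0.56 for a probe added for the snoRNA U46, 0.30 for the zebrafish miR-150 probe, 0.12 for the fish miR-22b probe and 0.0577 for a row named only by the number 1531. The tested miR-150 probe, above background on all 8 arrays, did not separate the groups. Its difference was 0.32 (SE 0.57), with -0.14, -0.59 and 1.43 on scan days 1, 2 and 3.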

How the results depend on the processing

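Settings chosen after seeing the data were those without both arrays of scan day 3, with the sample channel from the sum and product columns, with 50 added to both amplitudes, with the ratio of the amplitude columns, with a filter on nematode-only probes and with 1 probe per miRNA. Over 24 settings besides the main one, the count of miRNAs passing between VC and control in limma was 0 throughout, with 0 to 13 at an unadjusted p under 0.05 and a smallest adjusted p between 0.222 and 1.00. For VC+I3C against VC and against control it was 0 except on the ratio of the amplitude columns, where it was 1 in each (miR-101a), whose reference cell on that array was 100. Lists between VC and control numbered 0 in the main setting and 1 with the sample channel alone after quantile normalization, in the authors' value table and with the sample channel from the sum and product columns (the miR-200 family in all 3, adjusted p = 0.0127 in the last and 0.650 with an estimated correlation). The count was also 1 without the filter on dim probes (the neural list, 17 members, median -0.44, adjusted p = 0.0499, and 0.602 with an estimated correlation) and 1 without both arrays of scan day 3 (Dlk1-Dio3). Leaving out each array gave 0 to 2 lists, the 2 without VC 3 being Dlk1-Dio3 and raised in lung cancer (median 0.46, adjusted p = 0.00405, and 0.642 with an estimated correlation). The cause was not tested, beyond more probes being tested without the filter. Lists between VC+I3C and VC numbered 0 throughout. The Dlk1-Dio3 list also passed for VC+I3C against control with the sample channel from the sum and product columns (adjusted p = 0.0392, and 0.761 with an estimated correlation). The number of arrays closest to one of their own day was 4 in the main setting, 5 without the filter and 2 in the authors' table. With the replicate number as a block, 0 miRNAs passed between VC and control. This is the same comparison as with the scan day block, since same-numbered control and VC arrays share a scan day, and so no further check. For VC+I3C the replicate block pairs the array with control 1 and VC 1, of another scan day. Deviations of same-numbered control and VC arrays correlated at 0.68, 0.60 and -0.0458. Of 49 named miRNAs, 22 kept their sign between VC and control in every setting that gave a value. Not run were other background corrections and the share of called miRNAs nearer control, which had no calls to rest on. Signal over background of 11.1 to 17.65 and 3, 4 and 1 arrays limit what could be seen.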

Other observations

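Tests chosen after the result was seen are those of an exchange of arrays, of a single wrong label, of the VC+I3C array lying towards control, of other splits of the samples and of dim probes by the member above background on all arrays.

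A probe added for miR-21 and a fish miR-21 probe lay outside the tested probes. The added probe was 1.77, 2.82 and 4.73 on control 1 to 3, 3.88, 5.14, 4.30 and 5.45 on VC 1 to 4, and 4.53 on the VC+I3C array. Its differences between VC and control were 2.11, 2.32 and -0.43 on scan days 1, 2 and 3, and those of the fish probe 1.27, 0.75 and -0.56. In lists with too few tested members, VC and control differed by 0.34 (SE 0.77) for the endothelial miR-126-3p, -0.19 (SE 0.64) for the erythroid miR-451, 0.33 (SE 0.65) for the striated muscle miR-206, 0.27 (SE 0.55) for miR-182 of the miR-183 cluster and 0.44 (SE 1.76) for miR-34b, each with an adjusted p of 0.995 in limma. The difference was -0.44 (SE 0.79) for miR-216a of the liver and pancreas list and -1.07 (SE 1.21) for hsa-miR-371 of the embryonic stem cell cluster, with the same adjusted p, and the neural list had 0 tested members.

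Differences between VC and control on scan day 3 ran against the mean of days 1 and 2 across 160 miRNAs (r = -0.61, 95% interval -0.72 to -0.46). The main values were already normalized by loess on brightness within each array, and r was -0.69 after median centring without loess. It was -0.60 (-0.72 to -0.44) once any remaining trend with brightness was removed. These values argue against a trend with probe brightness. Noise near background is argued against too, as r was -0.49 (-0.66 to -0.29) over 74 miRNAs above background on all arrays. A single wrong label would leave both day 3 arrays in 1 group, with a slope near 0 only if arrays of 1 group did not differ along this pattern. The slope was -0.85 (-1.03 to -0.64), but it rests on the same values that raised the question. VC 3 and VC 4, both labelled VC, did differ along the pattern, but the label of VC 3 is itself in question. Whether arrays of 1 group differ along the pattern is therefore not known, so the slope cannot decide on a single wrong label. An exchange of the arrays labelled control 3 and VC 3 is a candidate explanation that stays open, since it was raised by the same correlation and these data cannot settle it; relative to VC 4 of another day, r with the mean of days 1 and 2 was -0.57 for VC 3 and 0.12 (95% interval -0.00129 to 0.24) for control 3. Differences between animals, such as how much tumour a lung sample held, were not tested and stay open, and the labels were kept as given.

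Of the 9 members of the Dlk1-Dio3 list, 6 had higher values in VC on scan days 1 and 2 and lower on day 3, and the list was singled out of 11 after its medians of 2.07, 2.74 and -2.46 were seen. Of 10000 random lists matched on mean probe signal, 0% had medians of that sign pattern as large, with 0.57 the highest against 2.07. The 6 members were above background on 3 or 4 of the 8 arrays, and the 1 member above background on all 8, miR-494, differed by 0.18, -0.36 and 0.13 and did not follow, so the random lists do not exclude dim probes. Among the 6, hsa-miR-154* and miR-299 were above background on no control array, so the sign of their day 3 differences is uncertain. Joint expression of the cluster that differs between these lung samples is a hypothesis that was not tested further, and its direction with VC hangs on the open question of day 3.

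The VC+I3C array was set against VC 4 along the mean differences of scan days 1 and 2, which share no array with it. The correlation across 160 miRNAs was -0.0623 (95% interval -0.21 to 0.10), so a shift towards control could be neither shown nor excluded.

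Between VC and control 0 miRNAs and 0 lists passed, a count that all 35 of the 35 splits of the 7 arrays reach by construction, so the splits say nothing on chance. The highest other split gave 11 miRNAs and, for lists, the highest gave 5. The split with 11 followed scan days 1 and 2 against 3 and 4, and with scan day as a block the real grouping gave 0. The split that exchanges control 3 and VC 3 gave 9, and another gave 6 and the others 0. With the scan day block the exchange gave 13, the highest, tied with the split that also puts VC 4 on the other side, which is the same comparison under the block because VC 4 is the only 1 of the 7 arrays on its day. A further 2 splits gave 3 with the block. The exchange was raised by the opposite differences of day 3 in these same values, so its counts of 9 and 13 are no added evidence for it. At least 1 list passed in 19 of the 35 splits.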
